A study of Homo sapiens with 42 samples.

How the data were processed

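The material was DNA from KG-1, an established human acute myelogenous leukaemia cell line. Per the labels, cells were kept for 1 h in 100 µM etoposide, 20 µM mitoxantrone or vehicle. DNA was then pulled down with an antibody to topoisomerase 2A (TOP2A) or to topoisomerase 2B (TOP2B), or kept as input. Per the labels' protocols, chromatin was sonicated without formaldehyde, the eluted DNA was treated with TDP2, an enzyme that releases TOP2 from blocked 5′ ends, and digested with BsmAI, heated and sequenced as Illumina TruSeq libraries. Reads were 38 to 100 bp long, and most libraries had 50 bp reads.

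The values used were the deposited read count of each named region in each of the 42 libraries. Per the submitters' processing notes, reads were trimmed with Trimmomatic 0.36, aligned with BWA 0.7.17 to the T2T-CHM13 genome and counted with HTSeq, for which the version string 2.7.13 is given. The table holds 2523 centromeric and satellite regions, named by class and chromosome, and 5 tallies for reads that were given to no region. The minimum mapping quality, and whether reads or pairs were counted, are not given in the sources used here. Of all reads in a library, 29.1% to 73.4% fell in no named region, 21.1% to 68.3% were set aside for low mapping quality and 0.00273% to 0.0520% were ambiguous. The classes of the reads set aside are not given, so class shares describe only the reads that passed and not the full content of a class. No normalisation had been applied to the counts. Region coordinates and base composition were not used here.

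Libraries were grouped by drug series, treatment and library kind into 12 groups, with 4 libraries in each etoposide-series group and 3 in each mitoxantrone-series group. Each of the 7 replicas held 6 libraries, and each was sequenced within 1 of 5 sequencing orders. The shared replica label in the sample annotation pairs the libraries. In a check of this pairing, 18 of 21 pairs of drug and no-drug libraries had a correlation above 0.1 across regions after removal of the group means, from -0.590 to 0.956, and 17 had their highest value with the library of the same number. The pairs that had not were all of etoposide replicas 3 and 4, the only replicas of 1 series to share a sequencing order. Elsewhere the replicas of a series differed in order, so the check could not tell pairing from order or read length. Regions are not independent replicates. No 2 libraries of a group held the same counts in 54 pairs checked. The labels do not state whether replicas were grown and treated independently. The p-values therefore measure spread between samples, which may be technical.

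Regions were tested with edgeR 4.0.16 in R 4.3.3, by quasi-likelihood with TMM factors, after filterByExpr with a minimum count of 10. Unless a replica block is named, the edgeR and DESeq2 fits had no replica term, so differences between replicas added to the spread. Fewer small p-values than expected by chance are then no evidence that nothing changed. P-values were adjusted by the Benjamini-Hochberg method over the regions tested, at a threshold of 0.05, and all tests were two-sided. Each series was fitted on its own, with 1068 regions tested in 24 etoposide-series libraries and 1416 in 18 mitoxantrone-series libraries; 1372 regions were tested in the joint fit of 42 libraries. The 18 comparisons were drug against no drug in each library kind, the drug effect in pulldown minus that in input, the effect in TOP2A minus that in TOP2B, the etoposide effect minus the mitoxantrone effect, and pulldown against input without drug. The comparison of pulldown and input over the untreated libraries of all 7 replicas was added after the table was seen, with the replica as a block. DESeq2 1.42.0 and limma 3.58.1 (voom with quality weights and a replica block) were run beside edgeR. In the etoposide fit the median biological coefficient of variation was 0.527, against a counting coefficient of variation of 0.173 at the median mean count of 33.5 reads. In the mitoxantrone fit these were 0.638, 0.145 and 47.6 reads.

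For each class, the reads of its regions plus 0.5 were divided by all region reads of the library, and the log2 ratio was taken within each replica. Differences were tested by exact two-sided permutation of the sign within replicas, or of the labels where libraries were not paired. The smallest p these tests allow is 0.125 for 4 pairs, 0.25 for 3 pairs, 0.0156 for 7 pairs, 0.0286 for 4 against 4 libraries and 0.1 for 3 against 3. P-values were adjusted over the 12 classes of a comparison. There were 72 class tests of drug against no drug, 48 of effects minus input, 24 of TOP2A minus TOP2B, 24 of etoposide minus mitoxantrone and 72 of pulldown against input.

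The regions named were set by rule: up to 8 at each end among those past the threshold in the same direction in all pairs with a mean of at least 50 reads (3 at each end outside the drug comparisons of the pulldowns), the 5 with the highest mean CPM, and the 2 most abundant of each list. As no region passed the threshold, 17 regions were named, all by abundance. Lists fixed were alpha satellite, beta satellite, gamma satellite, human satellite 1, human satellites 2 and 3, other centromeric sequence (transition and unclassified satellite regions) and ribosomal DNA. They were tested with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, which asks whether a list moves on balance in 1 direction. The comparisons, region tests, lists and naming rule were set before the data were examined. The class shares with their tests, and the use of LSAU-BSAT composites, HSat5 and single classes as further lists, were chosen after the table was seen.

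The methods were tested on simulated data with the estimated spread, 4 libraries per group and 1018 regions. Each region was drawn on its own, with no shift of replicas or of composition. The rates therefore hold for such data and not for the real libraries, whose regions shifted together. There edgeR called 74 regions, 2 of them falsely, and DESeq2 called 85 with 5 false calls. Voom, here fitted without the replica block, called 65 with 0. Voom with the block, as used on the real libraries, was not simulated. Of the regions simulated 8-fold higher edgeR recovered 76.9%, and of those 4-fold higher 37.5%. It recovered 2.56% of those 2-fold higher, 51.4% of those 4-fold lower and 20.5% of those 2-fold lower. At a low spread, with a coefficient of variation of 0.1, edgeR called 169 regions with 3 false calls.

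Alternatives were DESeq2, voom, RLE factors, library totals alone, no filter, library sizes with the reads outside regions, a replica block, the block with a composition axis, fits of the compared groups alone, and each replica left out. The composition axis was the main component of variation among the centromeric transition regions. Confidence intervals of shares of single libraries are 95% Wilson intervals. They cover counting error only, since PCR reads without molecular identifiers are not independent molecules.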

Results

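Etoposide and mitoxantrone are TOP2 poisons, which hold topoisomerase 2 covalently on the DNA it has cut. KG-1 leukaemia cells were given either drug for 1 h. TOP2A is the form most abundant in dividing cells, and TOP2B is present in resting and dividing cells alike. Without formaldehyde, the DNA pulled down with either antibody was read as DNA on which the enzyme had been trapped, and the question was where in the centromeric satellites the drugs placed it. The etoposide series had 4 replicas and the mitoxantrone series 3. Each replica held TOP2A, TOP2B and input libraries, with and without drug. The counts lay in 2523 regions of 12 classes, named with their chromosome on the T2T-CHM13 genome. Shares and scaled counts are relative to the other reads of a library. A change in trapped enzyme that affected all regions alike could therefore not be seen.

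Libraries held 552909 to 59639786 reads, with a median of 9158659. Of these, 23900 to 3207823 lay in the named regions, with a median of 351072. Region reads were 6.63% to 8.30% of region and no-feature reads together. Centromeric transition regions, the mostly non-satellite DNA between and beside the satellites, took 86.2% to 97.2% of region reads. Monomeric alpha satellite, tandem repeats beside the centromeric arrays that lack a higher-order unit, had a median of 1.30%. Beta satellite had 0.988%, human satellite 3 (HSat3) 0.788%, gamma satellite 0.784%, higher-order alpha satellite 0.333%, ribosomal DNA 0.0653% and human satellite 1A (HSat1A) 0.0594%. At these depths the widest 95% Wilson interval of a library's share spanned 0.504 points for monomeric alpha satellite, 0.319 for HSat1A and 0.204 for gamma satellite. For ribosomal DNA it spanned 0.0675 points, wider than its median share.

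The share of alpha satellite reads varied far more between replicas than between library kinds. Monomeric alpha satellite ran from 0.303% to 4.13% of region reads. The main component of variation over 547 regions held 62.4% of the variance. Differences between the combinations of replica and treatment took 83.9% of that component, the 12 groups 11.9%, and the library kinds 0.130%. The replicas alone took 64.2% and the sequencing orders 58.4%. No replica was split between orders, so the replica share includes that of the orders. Most of it could therefore not be told from order or read length. In mitoxantrone replica 3, the log2 change of monomeric alpha satellite with drug was -2.43 in TOP2A, -2.71 in TOP2B and -1.93 in input. In etoposide replica 3 these values were 2.55, 2.17 and 1.22. In these 2 replicas the input, which no antibody had touched, had changes of the same sign as the pulldowns. Library kinds parted in other replicas: in etoposide replica 4 the values were -0.41 in TOP2A, 2.65 in TOP2B and 2.12 in input, and in mitoxantrone replica 2 they were -0.93, -0.59 and 0.17.

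**Figure D1:**
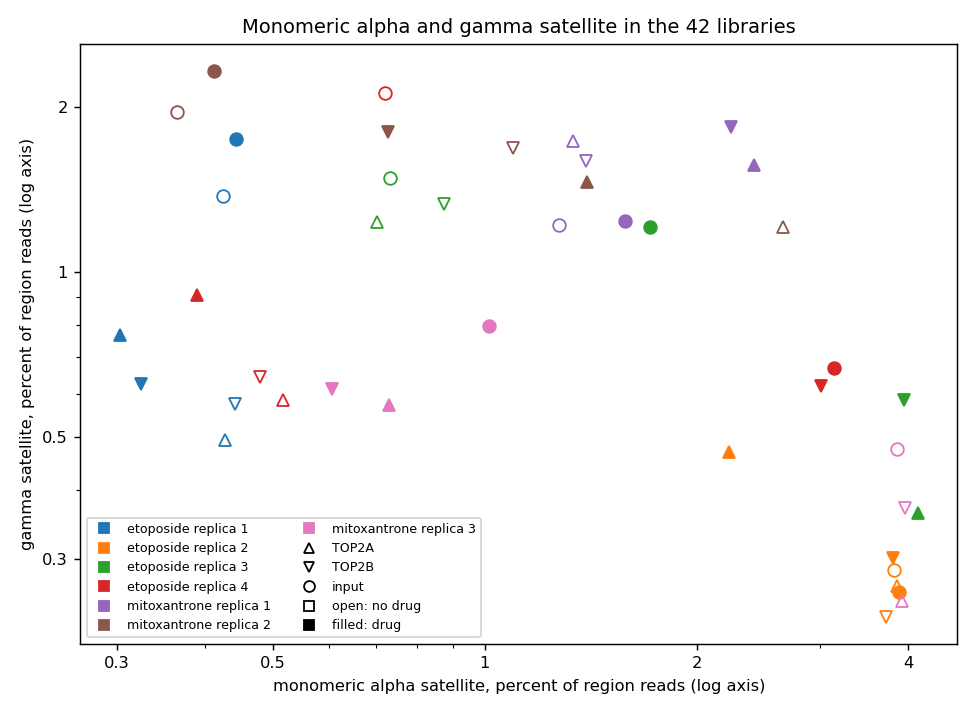
Share of region reads in monomeric alpha satellite (horizontal, percent, log axis) against gamma satellite (vertical, percent, log axis) in each of the 42 libraries, with colour for replica, shape for library kind and filled symbols for drug. Monomeric alpha satellite spans 0.303% to 4.13%, and libraries of 1 replica and treatment lie apart in some cases, as in etoposide replica 4 with drug (0.389% in TOP2A, 3.00% in TOP2B and 3.13% in input).

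With etoposide, the satellite classes in TOP2A pulldown were scattered on both sides of no change. Monomeric alpha satellite had a mean log2 change of 0.21 (1.16-fold, SD 1.57, n = 4), higher in 1 replica and lower in 3. Higher-order alpha satellite, the arrays on which kinetochores form, had 0.28 (SD 1.48), and HSat3, a short repeat in long arrays beside some centromeres, had 0.39 (SD 1.44). Gamma satellite, a GC-rich repeat, had 0.08 (SD 1.23), beta satellite -0.10 (SD 0.20) and the ribosomal DNA arrays 0.11 (SD 1.03). Centromeric transition DNA had -0.03 (SD 0.06), the narrowest spread.

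No class passed its exact two-sided test, where 4 pairs allow no p below 0.125. Among single regions, edgeR gave monomeric alpha satellite mon_8_1 a log2 change of 0.20 (SE 0.95) and mon_10_1 0.02 (SE 0.83). The most abundant transition region, ct_8_1 on a short arm, had -0.06 (SE 0.26). The HSat3 region hsat3_9_3 had 1.35 (2.54-fold, SE 1.00), the HSat2 region hsat2_1_6 1.12 (SE 0.99) and the AT-rich HSat1A region hsat1A_3_2 2.89 (7.42-fold, SE 1.70). These fits are of group means; the means of the log2 changes within replicas were smaller, at 0.69 for hsat3_9_3 (SD 1.56, higher in 2 of 4), 0.26 for hsat2_1_6 (SD 1.83, higher in 2 of 4) and 1.29 for hsat1A_3_2 (SD 2.14, higher in 3 of 4). HSat1A and HSat1B reads in the sequencing order of etoposide replicas 3 and 4 did not increase with library depth, staying at 38 to 542 and 62 to 319 reads per library while region reads ran from 23900 to 575088.

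**Figure D2:**
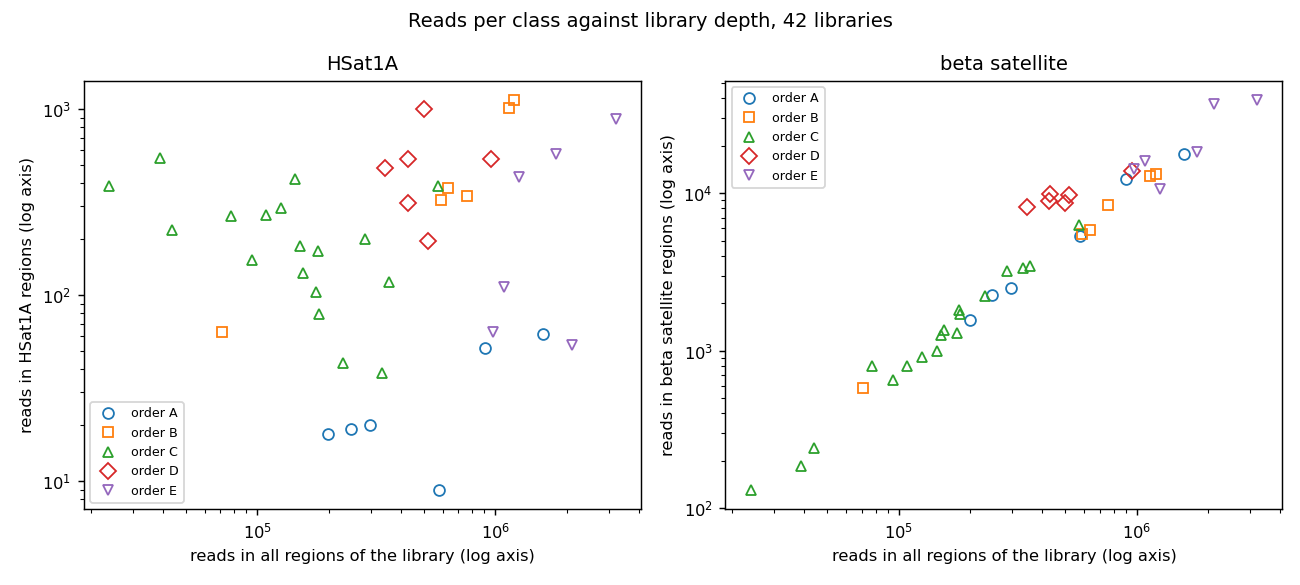
Reads in HSat1A regions (left) and in beta satellite regions (right) against the reads in all regions of a library, on log axes, with a symbol for each of the 42 libraries and colour for sequencing order. In the order with the shallowest libraries, HSat1A stays at 38 to 542 reads while region reads run from 23900 to 575088.

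EdgeR called 0 of 1068 regions in TOP2A, with 7 at an unadjusted p under 0.05, where 53.4 are expected by chance. As this fit had no replica term, the low count does not speak for a lack of effect. DESeq2 called 0 with 14 such regions, and voom with a replica block 0 with 74. Of the list of alpha satellite regions, 67 of 176 were higher and 109 lower, with a median of -0.22, against a mean class change of 0.24. Camera ranked the list below the other regions at an adjusted p of 2.66e-15, and at an adjusted p of 0.415 with an estimated correlation. Of the HSat2 and HSat3 list 44 were higher and 63 lower (median -0.19), with an adjusted p of 4.86e-11, and 0.415 as the adjusted p with an estimated correlation. Gamma satellite had 16 higher and 4 lower (median 0.30), at an adjusted p of 5.9e-07, and an adjusted p of 0.415 with an estimated correlation. Beta satellite had 38 higher and 32 lower (median 0.04), at an adjusted p of 4.72e-05, and an adjusted p of 0.175 with an estimated correlation. Other centromeric regions had 283 higher and 371 lower (median -0.05) but a camera direction upward, at an adjusted p of 2.87e-08, and an adjusted p of 0.0590 with an estimated correlation. Human satellite 1, with 28 of 36 higher (median 1.39), and ribosomal DNA, with 1 of 5 higher (median -0.08, camera direction upward), had adjusted p of 0.688 and 0.164. With a replica block, camera at the preset correlation gave other adjusted p. They were 2.71e-08 for human satellite 1 (upward), 0.0558 for HSat2 and HSat3 and 0.574 for other centromeric regions. The drug library of replica 3 held 1.61% HSat1A, where the highest other of its group had 0.0887%. Within replicas the most abundant HSat1A region, hsat1A_13_1, had a mean of 0.10 (SD 2.69, higher in 2 of 4). Adjusted over the list alone, 0 members were called in each of the 7 lists, in this and the other list comparisons. Without replica 3, the mean of monomeric alpha satellite was -0.57, that of higher-order alpha satellite -0.37, that of HSat3 -0.32, that of beta satellite -0.02, that of ribosomal DNA 0.53 and that of gamma satellite 0.70.

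**Figure D3:**
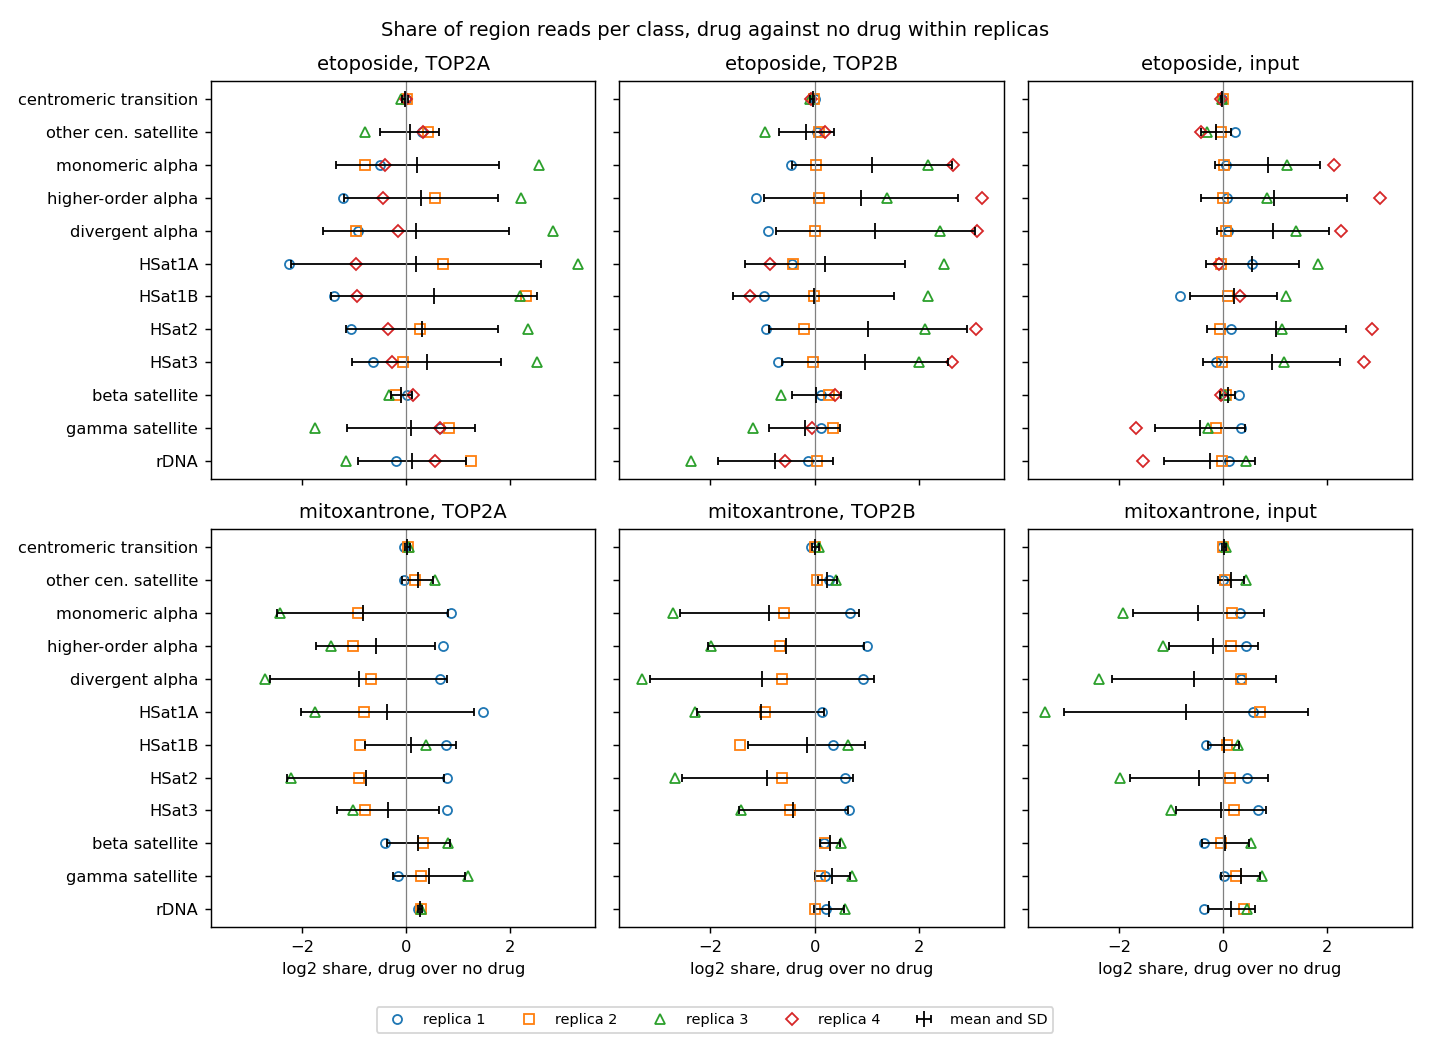
Log2 ratio of each class's share of region reads, drug over no drug (horizontal), for 12 classes (vertical) in TOP2A, TOP2B and input, for etoposide (n = 4 replicas) and mitoxantrone (n = 3); open symbols are replicas, bars the mean and SD. Monomeric alpha satellite spans -0.79 to 2.55 in etoposide TOP2A and -2.43 to 0.85 in mitoxantrone TOP2A, while centromeric transition DNA stays near 0.

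In TOP2B pulldown with etoposide, monomeric alpha satellite had log2 changes of -0.45, 0.03, 2.17 and 2.65 in replicas 1, 2, 3 and 4. The increase thus lay in replicas 3 and 4, which shared a sequencing order. Monomeric alpha satellite had a mean log2 change of 1.10 (2.14-fold, SD 1.54, n = 4), divergent higher-order alpha satellite 1.16 (2.24-fold, SD 1.91) and higher-order alpha satellite 0.89 (1.85-fold, SD 1.86). HSat2 had 1.02 (SD 1.90) and HSat3 0.97 (SD 1.59). Ribosomal DNA had -0.76 (0.592-fold, SD 1.10), lower in 3 of 4 replicas, and gamma satellite -0.19 (SD 0.68). The exact paired p was 0.375 for monomeric alpha satellite and 0.25 for ribosomal DNA. Transition DNA had -0.04 (SD 0.05) as a share of region reads, and 0.08 as a share of all reads. Without replica 4 the means were 0.59 for monomeric, 0.51 for divergent and 0.11 for higher-order alpha satellite, 0.33 for HSat2 and 0.42 for HSat3. Without replica 3 they were -0.22 for ribosomal DNA and 0.14 for gamma satellite.

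The single regions given here had fitted values of the same sign as their class means, but not of the same size. For mon_8_1 the log2 change was 1.00 (2.01-fold, SE 0.95), for mon_10_1 0.92 (SE 0.82) and for hsat3_9_3 1.41 (2.65-fold, SE 0.99). For rDNA_13_1 it was -1.72 (0.303-fold, SE 1.02), for rDNA_21_1 -1.16 (0.448-fold, SE 0.75) and for gsat_8_7 -0.47 (SE 0.68). Within replicas the mean was -1.11 for rDNA_13_1 (SD 0.73, lower in 4 of 4), -0.62 for rDNA_21_1 (SD 1.46, lower in 2 of 4) and -0.18 for gsat_8_7 (SD 0.65, lower in 1 of 4). Of 1068 regions, edgeR called 0, with 7 at an unadjusted p under 0.05, DESeq2 called 0 with 8, and voom 0 with 14. The alpha satellite list had 171 of 176 members higher (median 0.78), at an adjusted p of 5.36e-12, and an adjusted p of 0.560 with an estimated correlation. The HSat2 and HSat3 list had 3 members lower and the rest higher (median 0.72), at an adjusted p of 1.39e-05, and an adjusted p of 0.564 with an estimated correlation. Human satellite 1 had 32 of 36 higher (median 1.43), yet camera ranked it downward at an adjusted p of 0.00141, and an adjusted p of 0.564 with an estimated correlation. At the preset correlation with a replica block, its adjusted p by camera was 0.451. The drug library of replica 3 held 1.39% HSat1A, where the highest other of its group had 0.0447%. Within replicas hsat1A_3_2 had a mean of -0.27 (higher in 1 of 4) and hsat1A_13_1 one of 0.25 (higher in 2 of 4). Other centromeric regions had 421 of 654 lower (median -0.15), at an adjusted p of 5.33e-11, and at 0.0168 as adjusted p with an estimated correlation (0.00340 with a replica block). Ribosomal DNA had 5 of 5 lower (median -1.16), at an adjusted p of 0.0190, and an adjusted p of 0.560 with an estimated correlation.

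The etoposide input libraries gave the level of the same classes without a pulldown. Monomeric alpha satellite had a mean log2 change of 0.86 (1.81-fold, SD 1.01, n = 4), higher-order alpha satellite 0.98 (1.98-fold, SD 1.40) and divergent alpha satellite 0.95 (1.94-fold, SD 1.08), each higher in 4 of 4 replicas. HSat2 had 1.02 (SD 1.33), HSat3 0.93 (SD 1.32) and gamma satellite -0.44 (SD 0.87). The exact paired p of the 3 alpha satellite classes was 0.125, the smallest that 4 pairs allow, and 0.375 after adjustment. In replicas 1 and 2 the monomeric values were 0.06 and 0.02, and in replicas 3 and 4, from another sequencing order, 1.22 and 2.12. Without replica 4 the mean was 0.44 for monomeric, 0.31 for higher-order and 0.52 for divergent alpha satellite, 0.41 for HSat2, 0.34 for HSat3 and -0.03 for gamma satellite. Among these inputs edgeR called 0 of 1068 regions with 0 at an unadjusted p under 0.05, DESeq2 0 with 0, and voom 0 with 71. The alpha satellite list had 172 of 176 higher (median 0.64), at an adjusted p of 7.49e-18, and an adjusted p of 0.386 with an estimated correlation. Other centromeric regions had 384 of 654 lower (median -0.08), at an adjusted p of 3.87e-15, and 0.00451 as adjusted p with an estimated correlation (0.00473 with a replica block).

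With mitoxantrone, alpha satellite in TOP2A pulldown was lower in 2 of 3 replicas. Monomeric alpha satellite had a mean log2 change of -0.83 (0.562-fold, SD 1.64, n = 3), divergent alpha satellite -0.91 (0.532-fold, SD 1.70) and higher-order alpha satellite -0.59 (0.666-fold, SD 1.14). Ribosomal DNA, which holds the genes of the large ribosomal RNAs, had 0.27 (1.20-fold, SD 0.03), higher in 3 of 3 replicas. HSat5, a minor satellite family, had 0.68 (1.60-fold, SD 0.71), and gamma satellite 0.44 (1.36-fold, SD 0.69). Without replica 3 these were 0.43 and 0.06, and divergent and higher-order alpha satellite had -0.01 and -0.16. The exact paired p of ribosomal DNA was 0.25, the smallest that 3 pairs allow. For mon_8_1 edgeR gave -0.90 (0.537-fold, SE 0.73), for mon_10_1 -0.96 (0.515-fold, SE 0.66), for gsat_8_7 0.34 (SE 0.81) and for ct_8_1 0.19 (SE 0.29).

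EdgeR called 0 of 1416 regions in mitoxantrone TOP2A, with 5 at an unadjusted p under 0.05, where 70.8 are expected by chance; DESeq2 called 0 with 7, and voom 0 with 20. The alpha satellite list had 212 of 237 members lower (median -0.71), at an adjusted p of 2.59e-43, and an adjusted p of 0.168 with an estimated correlation. Gamma satellite had 27 of 41 lower (median -0.32) while camera ranked it upward, at an adjusted p of 1.59e-06, and an adjusted p of 0.590 with an estimated correlation. Other centromeric regions had 467 of 833 higher (median 0.06), at an adjusted p of 9.19e-12, and 0.0151 as adjusted p with an estimated correlation, but an adjusted p of 0.364 with that and a replica block. Without replica 3, the mean of monomeric alpha satellite was -0.04, and without replica 1 it was -1.68.

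In TOP2B pulldown with mitoxantrone, beta satellite had a mean log2 change of 0.29 (1.23-fold, SD 0.19, n = 3), and its LSAU-BSAT composites, in which beta satellite is joined to the LSAU repeat, had 0.37 (1.29-fold, SD 0.21). Gamma satellite had 0.34 (1.27-fold, SD 0.33), HSat5 0.39 (1.31-fold, SD 0.30) and ribosomal DNA 0.27 (1.21-fold, SD 0.29). These 5 were higher in 3 of 3 replicas, each at an exact p of 0.25. Without replica 3 the means were 0.19 for beta satellite, 0.15 for gamma satellite, 0.24 for HSat5 and 0.11 for ribosomal DNA. Monomeric alpha satellite had -0.87 (0.546-fold, SD 1.71) and HSat1A -1.03 (0.488-fold, SD 1.22). For mon_8_1 the log2 change was -0.97 (0.512-fold, SE 0.73), for mon_10_1 -0.98 (0.506-fold, SE 0.66) and for the composite bsat_22_6 0.39 (1.31-fold, SE 0.62). In this pulldown edgeR called 0 of 1416 regions with 3 at an unadjusted p under 0.05, DESeq2 0 with 3, and voom 0 with 51. The beta satellite list had 14 of 118 lower and the rest higher (median 0.38), at an adjusted p of 7.09e-08, and an adjusted p of 0.121 with an estimated correlation. The alpha satellite list had 202 of 237 lower (median -0.62), at an adjusted p of 6.29e-47, and an adjusted p of 0.121 with an estimated correlation. Other centromeric regions had 500 of 833 higher (median 0.08), at an adjusted p of 3.71e-16, and 0.00420 as adjusted p with an estimated correlation, but an adjusted p of 0.205 with that and a replica block. Without replica 3, monomeric alpha satellite had a mean of 0.05 and HSat1A one of -0.40, and without replica 1 these were -1.65 and -1.62.

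The mitoxantrone inputs had a mean of -0.48 for monomeric alpha satellite (0.717-fold, SD 1.26, n = 3), lower in 1 of 3 replicas, and 0.24 without replica 3. Gamma satellite had 0.34 (SD 0.37; 0.13 without replica 3) and HSat5 0.42 (SD 0.23), both higher in 3 of 3 replicas at an exact p of 0.25. In these inputs edgeR called 0 of 1416 regions with 1 at an unadjusted p under 0.05, DESeq2 0 with 1, and voom 0 with 21. The alpha satellite list had 223 of 237 lower (median -0.79), at an adjusted p of 2.09e-44, and an adjusted p of 0.160 with an estimated correlation. Other centromeric regions had 436 of 833 higher (median 0.01), at an adjusted p of 7.41e-14, and 0.00767 as adjusted p with an estimated correlation, but an adjusted p of 0.361 with that and a replica block.

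The drug effect in pulldown minus that in input asked which regions gained in pulldown, relative to other regions, beyond the shift of the input. For etoposide, monomeric alpha satellite had -0.64 in TOP2A (SD 1.58, n = 4) and 0.24 in TOP2B (SD 0.63). Gamma satellite had 0.52 in TOP2A (SD 1.57), and ribosomal DNA 0.37 in TOP2A (SD 1.64) and -0.50 in TOP2B (SD 1.61). Without replica 4, the TOP2A values were -0.01 for monomeric alpha satellite, -0.07 for gamma satellite and -0.21 for ribosomal DNA. Without replica 3, the TOP2B values were 0.01 for monomeric alpha satellite and 0.26 for ribosomal DNA. For mitoxantrone, LSAU-BSAT composites had 0.30 in TOP2A (SD 0.26, n = 3), higher in 3 of 3 replicas, and HSat3 had -0.37 in TOP2B (SD 0.34), lower in 3 of 3, each at an exact p of 0.25; without replica 2 they were 0.21 and -0.22. Of single regions, rDNA_13_1 had -1.46 in etoposide TOP2B (SE 1.40), mon_8_1 -0.52 in etoposide TOP2A (SE 1.34) and mon_10_1 -0.11 in mitoxantrone TOP2A (SE 0.92). EdgeR called 0 regions in each of the 4 comparisons, with 5 and 0 at an unadjusted p under 0.05 for etoposide TOP2A and TOP2B, and 0 and 0 for mitoxantrone. DESeq2 called 0 in each, with 5, 0, 0 and 0, and voom 0 in each, with 127, 19, 3 and 8.

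The effect in TOP2A minus that in TOP2B compared the 2 enzymes. Under etoposide, unclassified centromeric satellites had 0.22 (1.17-fold, SD 0.10, n = 4), higher in 4 of 4 replicas at an exact p of 0.125, adjusted to 0.938. Ribosomal DNA had 0.87 (1.82-fold, SD 0.62), higher in 3 of 4, and monomeric alpha satellite -0.89 (0.541-fold, SD 1.53), which was -0.16 without replica 4. Under mitoxantrone, HSat1A had 0.67 (1.59-fold, SD 0.61, n = 3), higher in 3 of 3 replicas at an exact p of 0.25 and at 0.34 without replica 1, and monomeric alpha satellite had 0.04 (SD 0.33). The region rDNA_21_1 had 1.15 under etoposide (SE 1.05), and bsat_1_1 had -0.39 under mitoxantrone (SE 0.85). EdgeR called 0 regions for either drug, with 6 and 0 at an unadjusted p under 0.05, DESeq2 0 with 10 and 1, and voom 0 with 42 and 4.

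Etoposide and mitoxantrone differ in structure, and they were used at 100 µM and 20 µM, so their effects could not be set against each other at a matched dose. The etoposide effect minus the mitoxantrone effect was 1.97 for monomeric alpha satellite in TOP2B (3.93-fold, exact unpaired p 0.229, n = 4 and 3), 1.92 for HSat2 (3.80-fold) and -1.03 for ribosomal DNA (0.491-fold, exact p 0.171, adjusted 0.490). In TOP2A it was 1.05 for monomeric alpha satellite (2.07-fold, exact p 0.457) and -0.42 for LSAU-BSAT composites (0.746-fold). Without mitoxantrone replica 3, monomeric alpha satellite had a difference of 1.05 in TOP2B (2.08-fold) and 0.25 in TOP2A, HSat2 1.04 in TOP2B and LSAU-BSAT composites -0.07 in TOP2A. Without etoposide replica 3, ribosomal DNA had -0.49 in TOP2B. For mon_8_1 the difference was 2.09 in TOP2B (SE 1.33) and 1.05 in TOP2A (SE 1.32), and for rDNA_13_1 it was -1.84 in TOP2B (SE 1.58). EdgeR called 0 of 1372 regions in either comparison, with 6 and 10 at an unadjusted p under 0.05, where 68.6 are expected by chance. DESeq2 called 0 with 9 and 9, and voom 0 with 23 and 46. Only the order with etoposide replicas 3 and 4 and mitoxantrone replica 2 held both drugs, and within it edgeR called 0, with 44 regions in TOP2A and 49 in TOP2B at an unadjusted p under 0.05. Each mitoxantrone arm there is 1 library, assumed to vary like the other groups, so this count says little about the drugs.

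Without drug, the pulldown libraries were set against input to ask where the antibodies enriched DNA. In the etoposide series, beta satellite was lower than input in 4 of 4 replicas, with a mean log2 ratio of -0.36 in TOP2A (0.779-fold, SD 0.14, n = 4) and -0.46 in TOP2B (0.728-fold, SD 0.15). LSAU-BSAT composites were lower in 4 of 4 replicas, at -0.76 in TOP2A (0.592-fold, SD 0.29) and -0.77 in TOP2B (0.585-fold, SD 0.41). Gamma satellite was at -0.93 (0.526-fold, SD 0.88) and -0.85 (0.553-fold, SD 0.76), also lower in 4 of 4, and at -0.61 and -0.56 without replica 4. HSat5 was at -1.03 in TOP2A (SD 1.13) and -0.97 in TOP2B (SD 0.77). In the mitoxantrone series LSAU-BSAT composites were at -0.51 in TOP2A (0.701-fold, SD 0.77, n = 3), HSat5 at -0.86 (0.550-fold, SD 0.70) and HSat1A at 2.24 (4.72-fold, SD 2.81), with 5.47 in replica 2. Without that replica LSAU-BSAT composites were at -0.21 and HSat1A at 0.63.

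The exact unpaired p of beta satellite in the etoposide series was 0.0286 in both pulldowns, the smallest that 4 against 4 libraries allow, and 0.343 after adjustment over the classes; the exact paired p was 0.125. For LSAU-BSAT composites the exact unpaired p was 0.0286 in both and the exact paired p, which keeps the pairing of the libraries, 0.125. Of single regions, bsat_1_1 had -1.12 in TOP2A (0.459-fold, SE 0.47) and -1.07 in TOP2B (0.475-fold, SE 0.47), bsat_22_6 -0.90 (SE 0.45) and -0.99 (SE 0.45), and gsat_8_7 -1.10 (SE 0.68) and -0.96 (SE 0.68). In the mitoxantrone series hsat1A_13_1 had 3.11 in TOP2A (8.65-fold, SE 1.43) and 2.59 in TOP2B (6.02-fold, SE 1.39), with the read numbers of HSat1A not rising with depth in the order of replica 2. EdgeR called 0 regions in the 4 comparisons, with 28 and 8 at an unadjusted p under 0.05 for etoposide-series TOP2A and TOP2B and 9 and 1 for the mitoxantrone series. DESeq2 called 0, with 46, 26, 16 and 7. Voom with a replica block called 14 regions in etoposide-series TOP2A and 6 in TOP2B, each lower than in input, and 0 and 0 in the mitoxantrone series, with 186, 142, 36 and 31 at an unadjusted p under 0.05. The 14 were 5 LSAU-BSAT composites, 5 gamma satellites, 1 HSat5 region and 3 other satellites, and the 6 in TOP2B were among them. The median of the beta satellite list was 0.24 in etoposide-series TOP2A against a class mean of -0.36 (the LSAU-BSAT composites held 194043 of the 312804 beta satellite reads). The gamma satellite list had 20 of 20 members lower in TOP2A (median -1.31), at an adjusted p of 1.35e-09, and an adjusted p of 0.796 with an estimated correlation. Other centromeric regions in mitoxantrone-series TOP2B had 528 of 833 lower (median -0.06), at an adjusted p of 1.11e-08, and 0.0454 as adjusted p with an estimated correlation, but an adjusted p of 0.526 with that and a replica block.

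**Figure D4:**
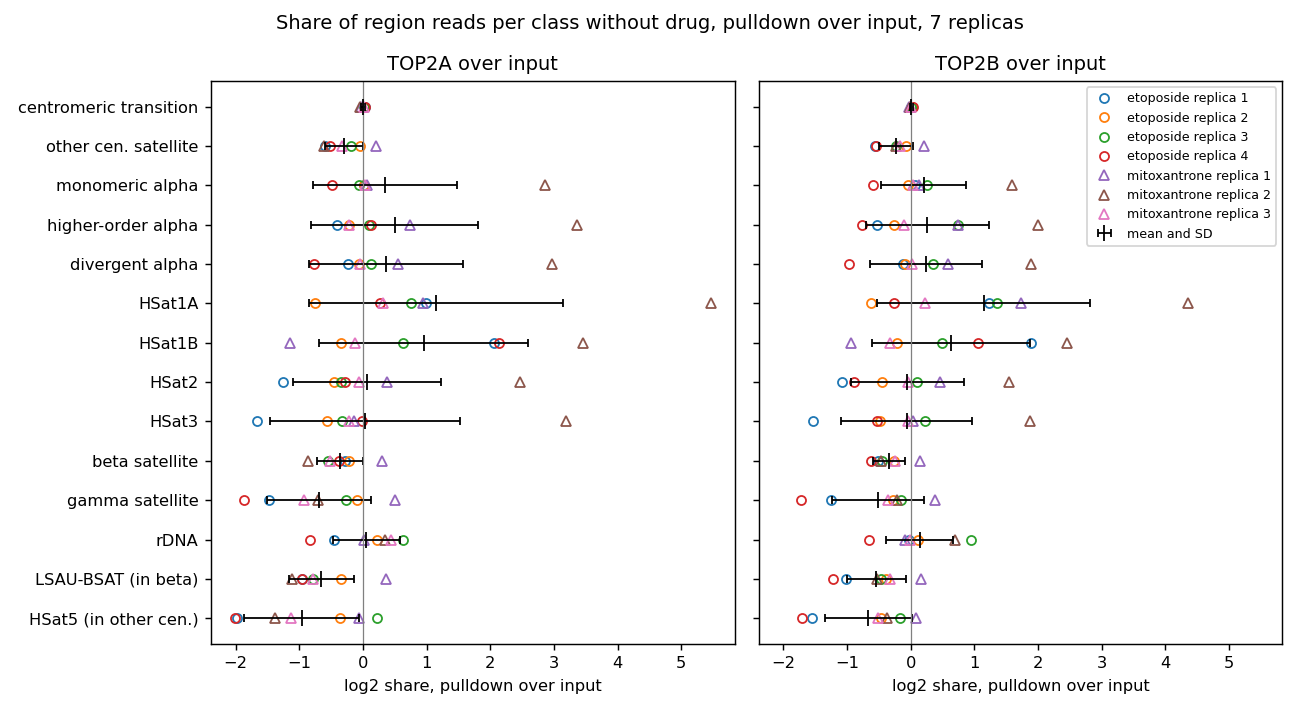
Log2 ratio of each class's share of region reads, pulldown over input without drug (horizontal), for 12 classes and 2 subsets (vertical) in TOP2A and TOP2B; symbols are the 7 replicas, bars the mean and SD. LSAU-BSAT composites lie below 0 in 6 of 7 replicas in both pulldowns, with means of -0.65 and -0.54, while HSat1A reaches 5.47 in TOP2A of mitoxantrone replica 2.

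Over the untreated libraries of all 7 replicas, LSAU-BSAT composites were lower in pulldown than in input in 6 of 7. Their mean log2 ratio was -0.65 in TOP2A (0.636-fold, SD 0.51, n = 7) and -0.54 in TOP2B (0.688-fold, SD 0.46). HSat5 was at -0.96 (0.514-fold, SD 0.90) and -0.67 (0.629-fold, SD 0.68), also lower in 6 of 7. Gamma satellite was at -0.69 (SD 0.82) and -0.51 (SD 0.72), and beta satellite as a whole at -0.36 (SD 0.36) and -0.34 (SD 0.26). The AT-rich HSat1A was at 1.14 in both (SD 2.00 and 1.67), higher in 6 of 7 replicas in TOP2A. Without mitoxantrone replica 2, from the order in which HSat1A reads did not increase with depth, it was at 0.42 in TOP2A and 0.61 in TOP2B. Gamma satellite was at -0.31 in TOP2B without etoposide replica 4.

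The exact paired p was 0.0469 for LSAU-BSAT composites and for HSat5 in TOP2A, and 0.0312 for both in TOP2B. For beta satellite it was 0.0625 and 0.0312, adjusted to 0.234 and 0.328, and for gamma satellite 0.0781 and 0.109. LSAU-BSAT and HSat5 were picked out after the table was seen. With the replica as a block, edgeR called 0 of 1028 regions in TOP2A, with 150 at an unadjusted p under 0.05, and 0 in TOP2B, with 71. Voom called 0 and 0, with 43 and 12. DESeq2 called 25 in TOP2A, each lower than input, with 158 at an unadjusted p under 0.05, and 0 in TOP2B, with 90. The 25 were 7 LSAU-BSAT composites, 2 HSat5 regions, 5 other unclassified satellites, 6 gamma satellites, 2 transition regions and 3 others. Without mitoxantrone replica 1, edgeR called 46 in TOP2A, of which 45 were lower and 22 were among the 25. The edgeR log2 ratio in TOP2A was -0.77 for bsat_1_1 (SE 0.18) and -0.72 for bsat_22_6 (SE 0.18), each at an adjusted p of 0.133, and in TOP2B -0.69 (SE 0.18) and -0.66 (SE 0.18), each at 0.462. TOP2A against TOP2B gave 0 calls by edgeR, DESeq2 and voom, with 2, 3 and 0 at an unadjusted p under 0.05.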

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

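The tests of explanations in this part were chosen after the results were seen. In groups of 4 libraries, a library stood apart when its gap to the nearest other took up most of the group's range (Dixon's test at 95%). Of 78 groups and quantities tested, 16 had such a library, where chance gives about 1 in 20, or 3.9. The mitoxantrone groups, with 3 libraries, were not tested. Shares below are percent of region reads with their 95% Wilson intervals.

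In the etoposide series, the untreated libraries of replica 2 were high in alpha satellite, HSat2 and HSat3. Monomeric alpha satellite was at 3.86% in TOP2A (3.81 to 3.90), 3.72% in TOP2B (3.68 to 3.77) and 3.82% in input (3.79 to 3.86), where the highest other libraries had 0.702%, 0.875% and 0.734%. Divergent alpha satellite was at 0.414% (0.398 to 0.431), 0.407% (0.392 to 0.423) and 0.431% (0.420 to 0.443). HSat2 was at 0.568% in TOP2A (0.550 to 0.588) and 0.777% in input (0.762 to 0.793). Higher-order alpha satellite in input was at 0.750% (0.735 to 0.766) and HSat3 at 1.72% (1.70 to 1.74).

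These libraries belong to a wider pattern, in which alpha satellite, HSat2 and HSat3 shift together, in input as well as in pulldown, though not always alike: with drug, etoposide replica 4 had a log2 change of monomeric alpha satellite of -0.41 in TOP2A but 2.65 in TOP2B and 2.12 in input. A difference between sequencing orders or read lengths as the whole cause was argued against by 2 replicas, etoposide 3 and mitoxantrone 3, in which all 3 library kinds differed by over 1 (log2) between drug and no drug within 1 order. The drug as the whole cause was argued against by the untreated inputs, whose log2 monomeric alpha satellite ranged over 3.17 in the etoposide series and 3.40 in the mitoxantrone series. A bias for or against AT-rich DNA may contribute and stayed open: over 14 replica and treatment means the slope on monomeric alpha satellite was 0.95 for HSat1A (SE 0.43, rank correlation 0.248), or 0.70 (SE 0.41) without the drug libraries of etoposide replica 3, but 0.11 for HSat1B (SE 0.31), which is AT-rich as well. As 4 of the 5 orders hold too few of these means, no slope within orders was fitted, and a difference between the cells of the cultures was not tested.

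The drug libraries of etoposide replica 3 were high in HSat1. HSat1A was at 1.61% in TOP2A (1.45 to 1.77) and 1.39% in TOP2B (1.28 to 1.51), where the highest other libraries had 0.0887% and 0.0447%. HSat1B was at 0.828% (0.721 to 0.952) and 0.746% (0.665 to 0.836). Ribosomal DNA in the input of that replica was at 0.133% (0.110 to 0.161). In the TOP2B drug library of replica 2, gamma satellite was low, at 0.301% (0.288 to 0.313), where the lowest other had 0.585%.

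These replica 3 libraries lie in the order with the shallowest libraries, in which HSat1A and HSat1B reads did not increase with depth over 18 libraries. The slope of log2 reads on log2 region reads was -0.44 (SE 0.20) for HSat1A and -0.12 (SE 0.14) for HSat1B. That of transition DNA was 1.02 and that of beta satellite 1.26. Slopes were also below 1 for HSat3 (0.41, SE 0.25), HSat2 (0.50, SE 0.25) and monomeric alpha satellite (0.55, SE 0.23). Higher-order and divergent alpha satellite both had 0.53 (SE 0.26). Whether depth bears on the shift of these classes was not tested. In the order of etoposide replica 1, HSat1B had a slope of 0.19 (SE 0.24). A number of HSat1 reads fixed up to counting error was argued against. Over the 18 libraries of the shallowest order, the variance of the reads over their mean was 87.6 for HSat1A and 29.9 for HSat1B. Counting error alone gives 1. A roughly constant number was not excluded: these libraries differ in replica, treatment and kind, and PCR reads are not independent, so a ratio above 1 arises either way. A higher share in pulldown as the whole cause was argued against, since the slopes with library kind and replica as terms were -0.39 (SE 0.41) and 0.0024 (SE 0.22). Reads added from other libraries and the retention of AT-rich DNA in libraries of low yield were not separated, and no biological explanation was tested.

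Reads set aside for low mapping quality, which no comparison used, took a larger share without drug in pulldown than in input in 4 of 4 etoposide replicas. The mean difference was 4.32 points for TOP2A (SD 4.36) and 1.87 points for TOP2B (SD 2.18), or 2.44 and 0.812 points without replica 3. In the mitoxantrone series the share was lower in pulldown in 2 of 3 replicas: 54.8% in TOP2A and 54.5% in TOP2B against 68.3% in input in replica 1, and 21.1% and 21.2% against 23.1% in replica 3. In replica 2 it was higher, at 47.6% and 46.7% against 37.8%. The 95% Wilson intervals of these shares were at most 0.254 points wide. In 36 combinations of class and library kind, the etoposide and mitoxantrone effects did not separate in opposite directions in all replicas and did not differ by the exact test.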

How the results depend on the processing

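Voom, the composition axis with the replica block, the comparison over 7 untreated replicas, fry, the blocked list tests, the denominators of class shares and the fit without 1 etoposide library were chosen after the table was seen. The other alternatives were planned.

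The count of 0 regions by edgeR in the 18 comparisons stayed 0 with DESeq2, RLE factors, library totals, no filter, library sizes with reads outside regions, a replica block, the block with the composition axis and each replica left out. It also stayed 0 in the 6 comparisons refitted on only the 2 groups compared and in the 10 refitted without 1 etoposide library. The smallest adjusted p over the 18 comparisons was 0.996 in the reported fit, 0.866 with DESeq2, 0.394 with the block, 0.0720 with the block and composition axis and 0.0135 with voom. With voom the count was 14 for TOP2A and 6 for TOP2B against input in the etoposide series, and the cause was not tested.

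For TOP2A against input over the 7 untreated replicas, the count was 25 with DESeq2 and 1 with the block and composition axis. That region, censat_7_3, was chosen after its values were seen and had a log2 ratio of -1.19 (SE 0.19) at an adjusted p of 0.00841. Over that result's alternatives the smallest adjusted p ran from 0.00627 to 0.998. Leaving out 1 replica gave 0 to 46 calls: 46 without mitoxantrone replica 1, 1 without etoposide replica 3 and 0 without each of the others. The 1 was the HSat5 region censat_19_2, at -2.45 (SE 0.37) and an adjusted p of 0.00679, also chosen after its values were seen. LSAU-BSAT composites were higher than input in mitoxantrone replica 1 alone in TOP2A. That replica was the only one with 100 bp reads. Its untreated share of reads of low mapping quality was 68.3% in input and 54.8% in TOP2A. The cause of the changed counts was not tested.

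Of 70 list tests, camera at its preset correlation called 50 both with and without the replica block, but not the same 50. With the block, in etoposide TOP2A, other centromeric regions (adjusted p 0.574) and HSat2 and HSat3 (0.0558) were no longer called. Human satellite 1 was called there (2.71e-08) only with the block. With an estimated correlation camera called 6, and with that and the block 2. Fry called 0 in either fit. The preset correlation is lower than the estimates, which ran from 0.0394 to 0.973, and the list calls depend on it.

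Among named regions, 2072 of 2141 values under alternatives stayed within the spread and on the same side of the threshold, 65 moved and 4 passed the threshold, these being bsat_1_1 and bsat_22_6 with voom; 256 changed sign, and none of those had been called. Among class means, 1012 of 1022 stayed within 1 SD, and the 10 that moved were of transition DNA with other denominators; 99 changed sign. As a share of all reads, LSAU-BSAT composites and HSat1B in etoposide TOP2B went from -0.06 to 0.06 and from -0.01 to 0.10.

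Counting error limits the scarce classes: HSat1A had 9 reads in 1 library, although that library held 577168 region reads. The spread between replicas limits the rest: the median SE of a log2 change was 0.673 in etoposide TOP2A and 0.858 in mitoxantrone TOP2A.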

Other observations

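The tests of the LSAU-BSAT and gamma satellite pattern in this part were chosen after the result was seen; the counts over other splits of the samples were planned, apart from those over the 7 untreated replicas.

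LSAU-BSAT composites and gamma satellite took a lower share in TOP2A pulldown than in input without drug. The composition shift between libraries, as far as it follows monomeric alpha satellite, was argued against as the whole cause for LSAU-BSAT. Its mean log2 ratio went from -0.65 to -0.60 (SD 0.48, lower in 6 of 7 replicas, exact p 0.0469) when that trend was taken out. LSAU-BSAT was picked as low in these same libraries, so this p is no independent support. The slope taken out was -0.15. It was fitted partly on these same libraries, and its error was not computed, which limits the argument. For gamma satellite the move was about as small, from -0.69 to -0.62 (SD 0.87, exact p 0.141). With its wider spread the question stayed open. A step that every pulldown shares, such as loss of some DNA on the beads, could give the same values in TOP2A and TOP2B. The TOP2A minus TOP2B difference of LSAU-BSAT was -0.11 (SD 0.34, exact p 0.406, n = 7), which leaves that step and a true lack of both enzymes open, as no pulldown without a TOP2 antibody is among the groups.

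Other splits of the same libraries into groups of the same sizes were tested with edgeR. Where the real count is 0, each split reaches it whatever the data, so these counts neither exclude chance nor speak for it, and only the highest other count is informative. For etoposide against no drug, 35 of 35 splits reached the real 0 in TOP2A, TOP2B and input, with highest others of 0, 0 and 405. The split with 405 set the drug inputs of replicas 2, 3 and 4 and the untreated input of replica 2 against the rest, and so points to a structure of the samples. It differs from the real split by 1 exchange, of drug replica 1 for untreated replica 2, and so cannot show whether that structure is apart from the drug. For the etoposide effect minus that in input, the 35 splits had highest others of 0 in TOP2A and 3 in TOP2B, and for TOP2A minus TOP2B of 0, beside a real 0. For mitoxantrone the highest others were 198 for TOP2A minus input, 18 for TOP2B minus input and 0 for TOP2A minus TOP2B, beside a real 0; the 198 and 18 also point to a structure of the samples. The etoposide effect minus the mitoxantrone effect, and TOP2A or TOP2B against input in the etoposide series, had a real 0 and highest others of 0 over 35 splits.

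For mitoxantrone against no drug, and for pulldown against input in the mitoxantrone series, the 10 splits are too few for a share under 0.05. The real counts were 0, and the highest other was 1 for TOP2A against input and 0 elsewhere.

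Over the 7 untreated replicas, the 64 swaps of labels within replicas likewise all reached the real 0 for TOP2A against input, TOP2B against input and TOP2A against TOP2B, with highest others of 70, 0 and 0. The 70 came from swapping mitoxantrone replica 1 alone, which points to that replica, the only one with 100 bp reads, as a structure of the samples. The regions at an unadjusted p under 0.05 gave a test that could come out either way: 7 of 64 swaps reached the real 150 in TOP2A (highest other 228), 10 of 64 the real 71 in TOP2B (highest other 120) and 44 of 64 the real 2 in TOP2A against TOP2B (highest other 7). By these counts chance could not be excluded in any of the 3.

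With etoposide, the share of reads of low mapping quality was lower in 4 of 4 replicas in TOP2B, by a mean of -5.92 points (SD 5.44, exact p 0.125, the smallest that 4 pairs allow), or -3.45 points without replica 3. It was lower in 3 of 4 replicas in input (mean -1.62 points, SD 2.25, and -0.565 without replica 3) and in 3 of 4 in TOP2A. In TOP2A the mean was -0.189 points (SD 16.5), with 23.3 points in replica 2, and -8.01 points (SD 6.54) without that replica. With mitoxantrone the means were 1.30 points in TOP2A (SD 3.25), -0.928 in TOP2B (SD 5.32) and -0.808 in input (SD 3.28), or -0.513, 1.93 and 1.05 without replica 1, 2 and 1.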
